A study of Mus musculus with 8 samples.

How the data were processed

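Single-cell RNA sequencing (10x Genomics droplets) was done on sorted tdTomato-positive, DAPI-negative, CD45-negative and Ter119-negative cells of Sox9-CreERT2;tdTomato mice, per the labels' protocols, at days 2, 7, 14 and 35 after a single dose of tamoxifen, with 1 library labelled male and 1 labelled female per day. The authors deposited raw count matrices, 1 per library, with whole-number UMI counts for 55574 features, among them a TDTOMATO feature, over 6794880 barcodes, with no filter on cells and no normalization. The matrices came from Cell Ranger 3.0.2 and the mm10 build, per the submitters' processing notes, and the gene annotation is not given in the sources used here. No cell annotation was used from the authors. Gene positions are from GENCODE release M21 on GRCm38, the assembly that mm10 names, and are 1-based. All columns of values were used.

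Library depth was 20900411 to 41150044 UMIs. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were called, 29609 in all and 1445 to 5317 per library. The mitochondrial filter removed 4.37%, 3.69%, 36.5% and 3.49% of barcodes in the libraries labelled male at days 2, 7, 14 and 35, and 2.62%, 13.2%, 26.2% and 24.6% in those labelled female. Doublets were scored per library with scrublet in scanpy 1.11.5, and the barcodes with the highest scores were removed, at 0.8% per 1000 called barcodes, 983 in all. Counts were log-normalized, 2000 variable genes and 30 principal components were taken, and a graph of 15 nearest neighbours was clustered with Leiden (leidenalg 0.10.2) at resolution 1, with no batch integration, which gave 32 clusters. Clusters were called X-like from 22 marker lists. A cluster with no clear class was left unnamed, which applied to clusters 0, 3, 9, 15 and 25.

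Cluster 0 held 3747 barcodes of the library labelled male day 35 and 1 barcode of another. Its median was 1550 UMIs against 5483 UMIs in the other kept barcodes of that library, and its profile correlated at r = 0.954 with that of barcodes of 10 to 100 UMIs, against 0.823 for chondrocyte-like cells. It was left out, a choice made after the data were seen. Of the 24878 cells left, those outside clusters named for hematopoietic or endothelial classes, and outside the unnamed cluster 25 (Siglech, Irf8, Bst2), were called mesenchymal, 21204 in all. Cluster 25 had no class among the marker lists and was set aside after the data were seen. It counts among the kept cells and in the hematopoietic-like percent of them, and in no mesenchymal value. The mesenchymal cells had a median of 4964.5 to 10332.5 UMIs per cell over the libraries. Within mesenchymal cells, clusters 3 (Msmp, Stc1, Myoc), 9 (Ibsp, Omd, Frzb) and 15 (Mmp13, Spp1, Mmp9) remained without a name and took 7.10%, 5.20% and 0.713% of mesenchymal cells at day 2 and 10.5%, 7.35% and 7.13% at day 35. Cluster 3 was highest at day 14, at 21.6%, and cluster 9 lowest at day 7, at 2.29%.

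Cells were not treated as replicates. Raw UMI counts were summed per library and class for libraries with at least 20 cells of the class, and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM scaling and filterByExpr, at a Benjamini-Hochberg adjusted p under 0.05. The day trend was the coefficient of log2(day) with a sex term from the labels, given as the log2 change over the span of 4.13 from day 2 to day 35. The sex effect was female minus male with day as a factor, and the interaction was that of sex with log2(day). All mesenchymal, chondrocyte-like, fibroblast-like, Lepr stromal-like and osteoblast-like cells were chosen beforehand, each to be tested if every day kept a library and each sex label kept at least 3, which the first 3 did. Articular or synovial-like, tenocyte-like and hypertrophic chondrocyte-like cells also met this and were added after the data were seen. Lepr stromal-like and osteoblast-like cells had too few cells at day 2, and only their shares are given. CPM per library are on TMM-scaled library sizes, except for Sox9, TDTOMATO, Ptprc, Xist and Ddx3y in the opening comparisons, which are CPM of the raw UMIs of the class. The median log2 change of all tested genes was under 0.03 for each comparison with either scaling.

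Shares of cells were tested by an exact permutation of days within each sex label (576 arrangements) on the slope of the logit share, with 0.5 added to each count, two-sided and adjusted over 15 classes. The sex difference of shares was tested by an exact sign-flip test over the 4 days. Intervals of shares are exact 95% (Clopper-Pearson) intervals, and a count of 0 was taken to allow 3 counts. For shares of cells with a UMI of Sox9 or TDTOMATO each cell was thinned to 2000 UMIs, which left out 869 mesenchymal and 1103 hematopoietic-like cells. The 28 gene lists named in the results were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation and with fry.

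The samples, tests, covariates, marker lists, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule took Sox9, TDTOMATO, Ptprc, Xist and Ddx3y in every case. For each day trend or sex effect it took up to 8 genes with the largest rise and 8 with the largest fall among those with adjusted p under 0.05 and a mean of at least 20 CPM, with the same sign in both sex labels or, for a sex effect, at all days, and no predicted genes. Where none passed it took the 3 genes of smallest p in each direction, and members of gene lists that passed could serve as examples. The minimum of 20 CPM did not apply to these. The value of 1 list member is not reported here.

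The edgeR step was tested on simulated counts with 200 changed genes. A simulated log2 change of 2 was recovered for 96% of genes in the mesenchymal day trend (16847 genes), 96% in the chondrocyte-like (14463) and 48% in the fibroblast-like day trend (4458), and a change of 1 for 37%, 39% and 4%. For the sex effect a change of 1 was recovered for 99%, 97% and 33% in the same classes, and for the interaction a change of 2 for 16%. The simulated sex changes followed the labels, which sex-linked genes went against or mixed in 3 libraries. This recovery therefore does not hold for differences between the sexes of the animals. The camera step called 3 of 3 raised lists and 0 of 27 unchanged ones, and the share test gave p under 0.05 in 5.5% of unchanged simulations.

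Other settings fixed then were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, leaving out each library, and cell filters of at least 2000 UMIs, of at least 500 UMIs with 250 genes and of at most 5% mitochondrial UMIs. They also included no doublet removal, Leiden resolutions of 0.5 and 2, equal numbers of cells, day as a factor, other sex and day terms, classes by marker score, all kept cells as the denominator, edgeR on cell counts, and other thinning. Chosen after the data were seen were the fits with cluster 0, without the 3 libraries whose sex-linked genes went against or mixed their labels, with the share of cells with Y-linked UMIs in place of the sex term, without day 14, with unnamed clusters among the shares, and the day trends of single clusters and further classes. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.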

Results

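Cells that had expressed Sox9, a transcription factor of the cartilage lineage, were followed in mouse limb bone by genetic labelling. Mice carried a tamoxifen-inducible Cre recombinase driven by Sox9 together with a tdTomato reporter, so that 1 dose of tamoxifen marked cells with active Sox9 and all of their later descendants. Viable tdTomato-positive cells without the blood antigens CD45 and Ter119 were sorted and profiled by droplet-based single-cell RNA sequencing. There were 8 libraries, with 1 labelled male and 1 labelled female at each of days 2, 7, 14 and 35 after tamoxifen. The design text of the series gives day 13 in place of day 14, and the labels name the tibia where the protocol speaks of hindlimbs. Sex-linked transcripts set the libraries labelled male and female apart at days 7 and 14, which points to separate animals there. Beyond this and the labels, nothing says that the libraries came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical. For the day trends this spread also holds departures of the days from a straight line on log2(day). The age of the animals was not given and moves with the day.

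Total UMIs were 25376620, 34775758, 26301273 and 20900411 in the libraries labelled male at days 2, 7, 14 and 35, and 31698613, 27130700, 41150044 and 25385323 in those labelled female. After filtering, 24878 cells were kept, of which 21204 were mesenchymal, with 718 to 4530 mesenchymal cells and 4619987 to 27144984 mesenchymal UMIs per library. The library labelled male day 35 was the smallest, because 3747 of its barcodes (81.0% of those kept there) formed a cluster that resembled free RNA and were left out. The pair of libraries of a day correlated across genes at r = 0.975 to 0.988, yet every pair differed by more than sampling noise (chi-square per degree of freedom at least 9.40). The first principal component of the mesenchymal sums held 43.3% of the variance and placed the day 2 libraries at -69.8 and -72.4 and the day 35 libraries at 50.3 and 48.6. Days 7 and 14 stood at 24.9 and -7.79 under the label male, out of order, and at 3.12 and 23.1 under the label female. The second component (24.1%) held days 2 and 35 at negative values and days 7 and 14 at positive ones.

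The sex-linked transcripts went against or mixed the sex label in 3 libraries. Xist, the long noncoding RNA that silences an X chromosome in female cells (X: 103460366 to 103483254), stood at 1251 CPM of mesenchymal UMIs in the library labelled male day 2, against 1.33 CPM or less in the other libraries labelled male. Ddx3y, a Y-linked helicase gene (Y: 1260771 to 1286629), stood at 97.9 CPM in the library labelled female day 2 and at 41.4 CPM in the library labelled female day 35, with 0 UMIs at days 7 and 14 in the libraries labelled female. Single cells separated into those with Xist alone and those with Y-linked transcripts alone. In the library labelled female day 2, 24.9% of mesenchymal cells with at least 2000 UMIs held Xist alone and 43.8% held Y-linked transcripts alone. In the library labelled female day 35 these shares were 49.5% and 27.6%. The library labelled male day 2 held 89.5% and 5.97% of such cells. Libraries are therefore named by their labels throughout, and every direction between sexes below is a direction between labels.

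**Figure D1:**
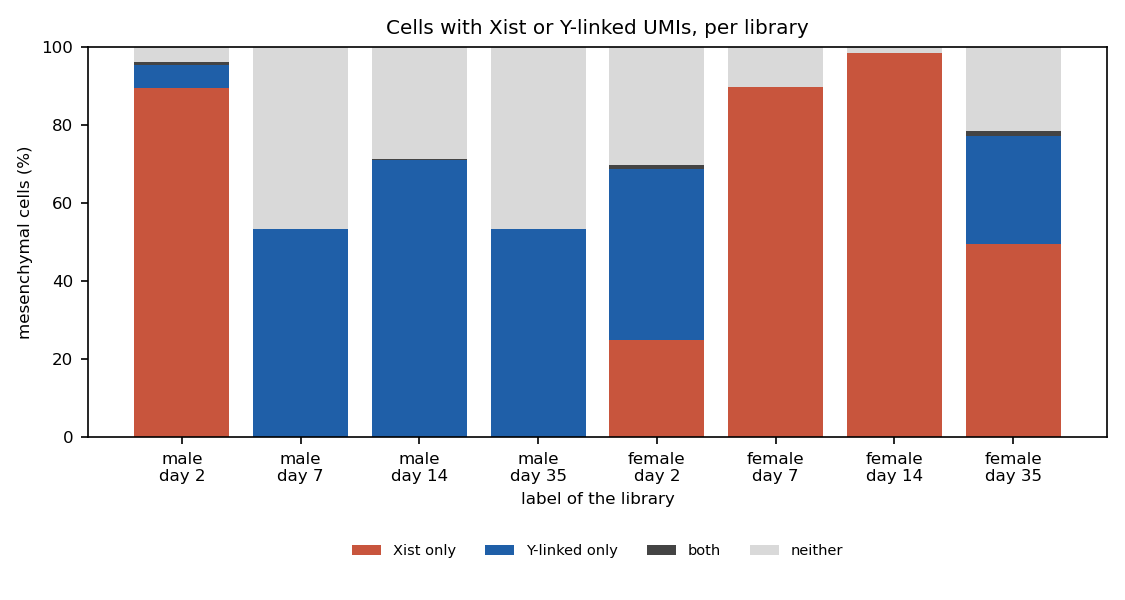
Percent of mesenchymal cells with at least 2000 UMIs (vertical axis) that held UMIs of Xist alone, of Y-linked genes alone, of both or of neither, as stacked bars, 1 bar per library. The libraries labelled male day 2, female day 2 and female day 35 held cells of both kinds, with 89.5%, 24.9% and 49.5% of cells with Xist alone.

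The first question was which cell classes the labelled population held at each day. Fibroblast-like cells (Dpt, Pi16, Clec3b and other markers of loose connective tissue) rose from 0.591% ± 0.417 of mesenchymal cells at day 2 to 5.86% ± 2.57 at day 35 (SD, n = 2 libraries per day). Osteoblast-like cells, led by the osteocalcin genes Bglap and Bglap2 and the bone gene Ifitm5, were not seen at day 2 and made up 4.37% ± 0.130 of mesenchymal cells at day 35 (SD, n = 2). Lepr stromal-like cells, the marrow stroma that makes Cxcl12, Kitl and Adipoq, stood at 0.0969% ± 0.102 at day 2 and 5.27% ± 0.957 at day 35 (SD, n = 2). Chondrocyte-like cells, with Acan and Col2a1, stood at 42.7% ± 2.54 at day 2, 53.3% ± 2.35 at day 7 and 20.4% ± 2.08 at day 35 (SD, n = 2).

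At day 2 there were 0 osteoblast-like cells among 2365 mesenchymal cells of the library labelled male and 0 among 4068 of the library labelled female, which allows shares of up to 0.127% and 0.0737%. At day 35 the shares were 4.46% (exact 95% interval 3.07 to 6.23) and 4.27% (3.40 to 5.30). Lepr stromal-like cells numbered 33 of 718 and 110 of 1849 at day 35, or 4.60% (exact 95% interval 3.19 to 6.39) and 5.95% (4.92 to 7.13), against 4 and 1 cells at day 2. Hypertrophic chondrocyte-like cells, which express Col10a1 and Ihh, stood at 0.809% ± 0.247 at day 2, 5.04% ± 1.65 at day 7, 7.61% ± 2.99 at day 14 and 7.17% ± 3.26 at day 35, and articular or synovial-like cells at 32.9% ± 1.03 at day 2, 8.62% ± 0.916 at day 7, 12.8% ± 2.21 at day 14 and 14.7% ± 1.10 at day 35 (SD, n = 2). Tenocyte-like cells with Tnmd and Kera stood at 9.85% ± 0.952 and 16.6% ± 3.84, and pericyte or smooth muscle-like cells at 0.0334% ± 0.0125 and 0.642% ± 0.316. Within the tenocyte-like class, cluster 4 (2213 cells) had 0 tenocyte markers among its leading genes, against 2 in cluster 11 (690 cells). All 6 listed tenocyte markers were detected in both, so most of the class is named from weaker evidence. Intervals and limits cover counting error only.

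Among the 15 named classes, the fibroblast-like share passed the test (log2 odds change from day 2 to day 35 of 3.58, SE 0.59; exact permutation p = 0.00174, the smallest this design gives; Benjamini-Hochberg adjusted p = 0.026, two-sided). The log2 odds changes of the other mesenchymal classes were 7.56 for osteoblast-like (adjusted p = 0.0521, exact permutation test), 0.85 for tenocyte-like (0.0521), 3.27 for hypertrophic chondrocyte-like (0.0846), 5.55 for Lepr stromal-like (0.134), -1.63 for chondrocyte-like (0.134), 3.79 for pericyte-like (0.134) and -1.42 for articular or synovial-like cells (0.272). None of these passed, and by highest marker score the tenocyte-like (-0.50) and pericyte-like (-0.088) changes turned direction, as did the tenocyte-like one (-0.40) with the cluster resembling free RNA. The endothelial-like share (4.14; 0.147) and the shares of blood cells did not pass either. By edgeR on the cell counts, 4 classes passed, namely osteoblast-like (7.90, adjusted p = 0.010), fibroblast-like (3.41, 0.0144), Lepr stromal-like (6.53, 0.0191) and pericyte-like cells (5.01, 0.0261). The fibroblast-like call was lost with at most 5% mitochondrial UMIs, with each cell classed by its highest marker score and with the cluster resembling free RNA included. Leaving out 1 library says nothing about its stability, since 1 class alone can then reach no adjusted p under 0.104 in the exact permutation test over 15 classes. Between the sex labels no share could pass, because the smallest p of the exact sign-flip test over 4 days is 0.125.

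**Figure D2:**
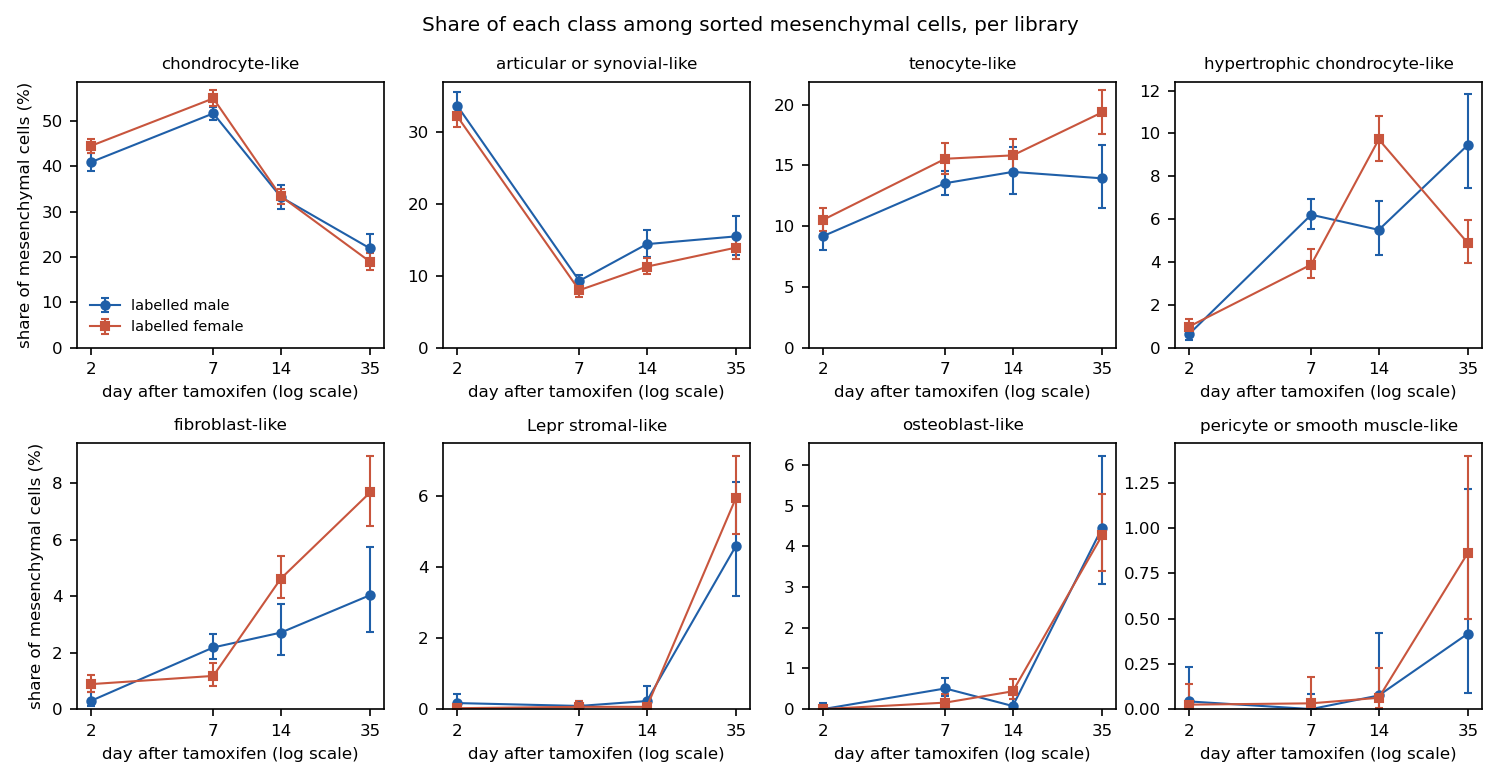
Percent of mesenchymal cells (vertical axis) in 8 classes against day after tamoxifen (horizontal axis), with 1 point per library, libraries labelled male and female drawn apart, and bars giving exact 95% intervals. Fibroblast-like, osteoblast-like and Lepr stromal-like cells were highest at day 35, at 4.04% and 7.68%, 4.46% and 4.27%, and 4.60% and 5.95% in the libraries labelled male and female.

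The sort excluded CD45-positive cells, yet hematopoietic-like cells made up 4.11% to 26.3% of kept cells. Their share was 21% and 19.9% at day 2 and 18% and 26.3% at day 35 in the libraries labelled male and female. Ptprc, which encodes CD45, stood at 434 CPM in these cells and at 0.355 CPM in mesenchymal cells. Hematopoietic-like cells were kept out of the fits of gene expression below and serve as background for the shares of cells with a Sox9 or TDTOMATO UMI.

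The next comparison asked whether Sox9 itself and the reporter stayed on in the labelled cells. Sox9 (11: 112782224 to 112787760) stood at 477 and 439 CPM of mesenchymal UMIs at day 2 and at 294 and 233 CPM at day 35 in the libraries labelled male and female. Over all mesenchymal cells its log2 change from day 2 to day 35 was -0.66 (SE 0.25; edgeR adjusted p = 0.138, n = 8), which did not pass. In chondrocyte-like cells it was -0.00 (SE 0.21; edgeR adjusted p = 0.999), and in fibroblast-like cells -1.59 (SE 0.48; edgeR adjusted p = 0.720, n = 7). In articular or synovial-like cells, a class added after the data were seen, Sox9 fell by 0.90 (SE 0.26; edgeR adjusted p = 0.0471). The clusters of this class changed in share with the day, and no fit within them was made. TDTOMATO, the reporter transcript, stood at 103 and 89.1 CPM at day 2 and 103.5 and 114 CPM at day 35, and did not pass in mesenchymal cells (0.32, SE 0.37; edgeR adjusted p = 0.629) or in chondrocyte-like cells (0.52, SE 0.34; 0.388). With days as separate groups, the Sox9 change from day 2 to day 35 over all mesenchymal cells passed (-0.81; edgeR adjusted p = 0.00227). Without the 3 libraries whose sex-linked genes went against or mixed their labels it was -0.02, in a fit that holds no library of day 2. With at most 5% mitochondrial UMIs the fitted change was -0.36 (edgeR adjusted p = 0.432).

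After each cell was thinned to 2000 UMIs, a Sox9 UMI was found in 49.8% of mesenchymal cells at day 2, 37.6% at day 7, 43.4% at day 14 and 29.3% at day 35, with 2 libraries pooled per day. Between day 2 and day 35 the share went from 55.5% to 34.9% in articular or synovial-like, from 49.4% to 44% in chondrocyte-like, from 33.9% to 17.8% in tenocyte-like and from 30.6% to 8.28% in fibroblast-like cells. In hematopoietic-like cells it was 3.07% (exact 95% interval 2.09 to 4.32) at day 2 and 0.976% at day 35. Free RNA at that level is argued against as the whole source in tenocyte-like cells (30.2 to 37.8 and 14.3 to 21.7). The fall of Sox9 in their fit did not pass (-0.69, SE 0.26, edgeR adjusted p = 0.431). In fibroblast-like cells, with 36 cells at day 2, free cartilage RNA was not excluded, and the fall is not read as their own expression. In hypertrophic chondrocyte-like cells the share was 50% and 62.7%. At day 35 it was 5.15% in Lepr stromal-like and 0.909% in osteoblast-like cells, against 0.976% in hematopoietic-like cells, so the osteoblast-like share is read as background. Pooled over the days, to which the classes contribute unequally, a TDTOMATO UMI was found in 22.5% of mesenchymal, 20.5% of chondrocyte-like, 24% of fibroblast-like, 16.4% of osteoblast-like and 12.5% of Lepr stromal-like cells, against 1.53% of hematopoietic-like cells. Median depths before thinning were 6127 UMIs in mesenchymal and 4489 UMIs in hematopoietic-like cells among those deep enough to be thinned. Without thinning, the Sox9 share differed between day 35 and day 2 by -23.8 percentage points, against -19.0 with thinning.

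**Figure D3:**
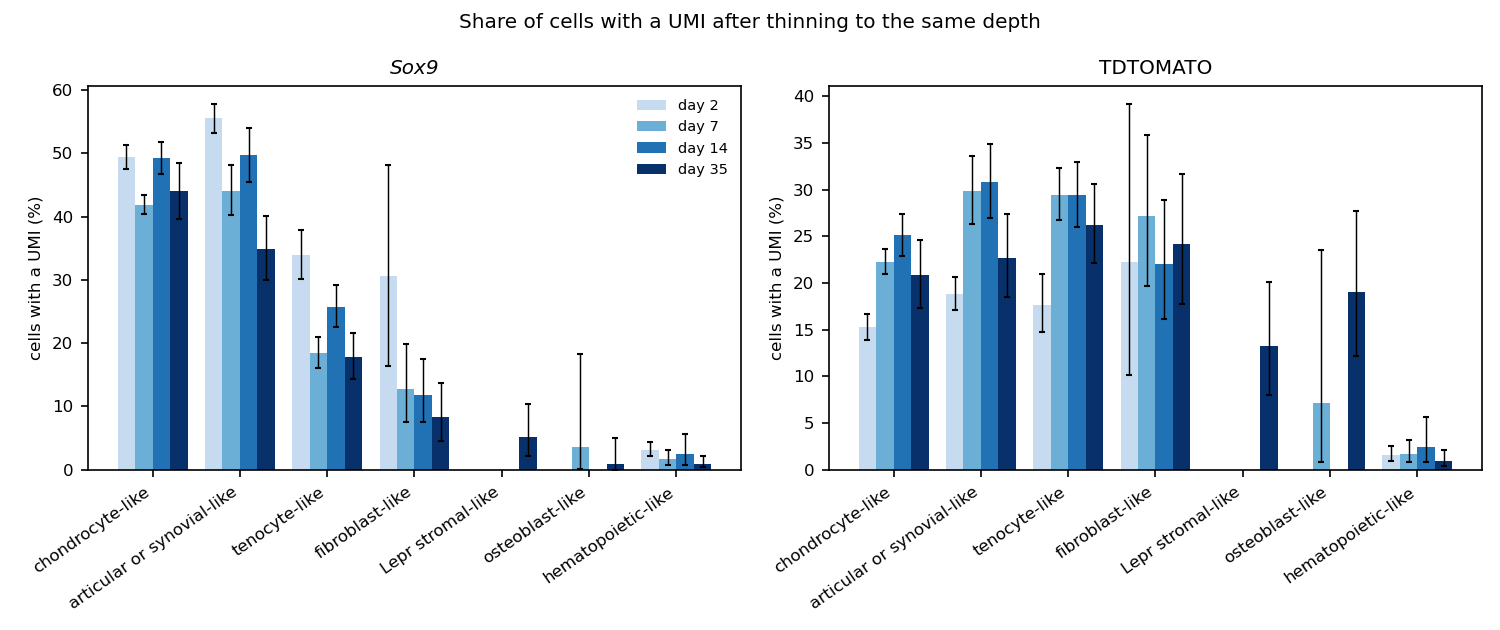
Percent of cells with at least 1 UMI of Sox9 or of TDTOMATO after thinning each cell to 2000 UMIs (vertical axes), as bars by cell class and day, with exact 95% intervals and bars drawn only for groups of at least 20 cells. At day 35 a Sox9 UMI was found in 44.0% of chondrocyte-like and 0.909% of osteoblast-like cells, and a TDTOMATO UMI in 20.8% and 19.1%.

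The main comparison asked which genes changed with the day in all mesenchymal cells. Bglap, which encodes the bone matrix hormone osteocalcin, went from 10.2 and 9.83 CPM at day 2 to 1344 and 866 CPM at day 35 in the libraries labelled male and female. Cxcl12, the chemokine that holds blood stem cells in the marrow, went from 35.2 and 27.2 CPM to 828 and 1130 CPM. Dlk1, an imprinted inhibitor of fat cell differentiation, went from 292 and 264 CPM to 6.0 and 6.84 CPM, and Rian, a noncoding RNA of the same imprinted region of chromosome 12, from 501 and 610 CPM to 70.9 and 65.5 CPM.

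In all, 1300 of 17315 genes passed (edgeR quasi-likelihood test on log2(day) with a sex term, adjusted p under 0.05, n = 8), of which 713 rose and 587 fell. Changes below are fitted log2 changes from day 2 to day 35. The largest rises under the naming rule were Car3, a carbonic anhydrase (7.71, SE 1.14), Adipoq, the adiponectin gene (6.73, SE 1.61), Bglap2 (6.65, SE 0.78), Bglap (6.37, SE 0.83) and Ifitm5 (5.76, SE 0.96). They were followed by the haptoglobin gene Hp (5.63, SE 0.97), Col22a1, a collagen gene (5.63, SE 0.67), and Cdh2, the gene of N-cadherin (5.24, SE 0.78), with edgeR adjusted p from 0.00375 to 0.0385. Bglap, Bglap2, Ifitm5 and Col22a1 are on the marker list of osteoblast-like cells, and Adipoq and Hp on that of Lepr stromal-like cells. These classes made up 4.37% and 5.27% of mesenchymal cells at day 35, against 0% and 0.0969% at day 2. The rises of these genes may therefore restate the shares, and no fit within either class was made. Bglap and Bglap2 are near-identical neighbours on chromosome 3 (88383501 to 88384464 and 88377736 to 88378699), so the split of UMIs between them is uncertain. The largest falls were Dlk1 (-5.37, SE 0.28), the BMP-binding gene Chrdl2 (-3.41, SE 0.53), Aoc2, an amine oxidase (-3.18, SE 0.54). Then came Rian (-2.92, SE 0.23), Moxd1, a monooxygenase (-2.77, SE 0.22), Mirg (-2.73, SE 0.25), the BMP antagonist Grem1 (-2.66, SE 0.30) and the imprinted noncoding RNA H19 (-2.62, SE 0.59), with edgeR adjusted p from 0.000183 to 0.0309. Dlk1 (109452823 to 109463336), Rian (109603940 to 109661716) and Mirg (109729764 to 109749460) are neighbours on the plus strand of chromosome 12.

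**Figure D4:**
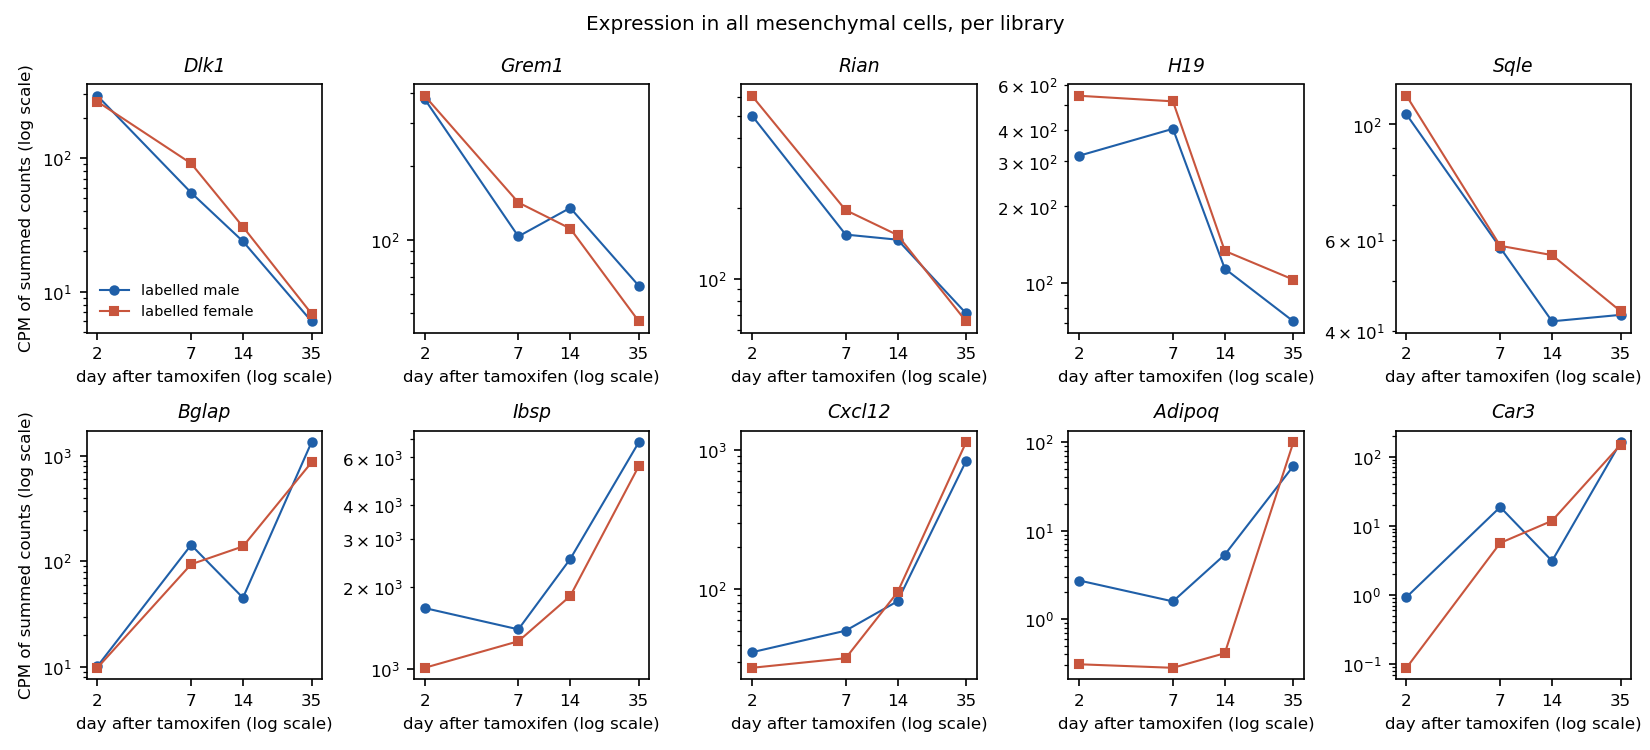
Expression in CPM of summed mesenchymal UMIs (vertical axes, log scale) against day after tamoxifen (horizontal axis) for 10 genes, with 1 point per library and libraries labelled male and female drawn apart. Dlk1 was at 292 and 264 CPM at day 2 and at 6.0 and 6.84 CPM at day 35, while Bglap went from 10.2 and 9.83 CPM to 1344 and 866 CPM.

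Of the 27 gene lists tested, 9 passed camera with a preset correlation of 0.01. None passed with an estimated correlation, where the lowest adjusted p was 0.226, and 8 of the 9 also passed fry. Among hematopoietic niche factors, 7 of 10 rose and 0 fell, also when adjusted over the list alone: Cxcl12 (4.87), the lymphoid growth factor Il7 (4.47, at a mean of only 2.06 CPM), the stem cell factor gene Kitl (4.13) and the adhesion gene Vcam1 (4.02) led (camera adjusted p = 0.000167; adjusted p = 0.226 with an estimated correlation). These cells pool classes whose shares changed, with Lepr stromal-like cells at 0.0969% at day 2 and 5.27% at day 35. Cxcl12 did not pass within chondrocyte-like (0.46) or fibroblast-like cells (0.28), and rose within articular or synovial-like cells (4.18). The clusters of that last class changed in share with the day and were not fitted alone. Of the hypertrophy list, 5 of 10 rose and 7 when adjusted over the list alone, with the collagenase gene Mmp13 at 3.20, the parathyroid hormone receptor gene Pth1r at 2.21 and Spp1 at 1.93 (camera adjusted p = 0.000104; adjusted p = 0.226 with an estimated correlation). Of the bone matrix and mineralization list, 8 of 15 rose, and 9 rose and 2 fell when adjusted over the list alone, with the bone transcription factors Sp7 (3.25) and Runx2 (2.35) and the matrix genes Ibsp (2.19) and Alpl (2.16) among those that rose (camera adjusted p = 0.00171; adjusted p = 0.490 with an estimated correlation). Of the osteocyte list, 4 of 7 rose, and 4 rose and 1 fell when adjusted over the list alone, with Dmp1 at 4.25 and the osteoclast factor gene Tnfsf11 at 3.30 (camera adjusted p = 0.0392; adjusted p = 0.476 with an estimated correlation). Of the adipogenic list, 5 of 10 rose, and 7 rose and 1 fell when adjusted over the list alone, with the lipase gene Lpl at 4.75, the leptin receptor gene Lepr at 3.37 and Fabp4 at 2.21 (camera adjusted p = 0.00213; adjusted p = 0.226 with an estimated correlation). Of the Notch targets, 1 of 5 rose, Heyl (3.95, at a mean of only 2.63 CPM), and 2 when adjusted over the list alone (camera adjusted p = 0.0227; adjusted p = 0.734 with an estimated correlation).

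Of the genes of sterol and fatty acid synthesis, 6 of 12 fell and 0 rose, and 8 fell when adjusted over the list alone. They included Sqle, squalene epoxidase (-1.36), Fdft1, squalene synthase (-1.30), and Hmgcs1 (-1.29) (camera adjusted p = 0.000104; adjusted p = 0.286 with an estimated correlation). Of the hypoxia and glycolysis list, 3 of 14 fell, also when adjusted over the list alone: the carbonic anhydrase gene Car9 (-3.12, at a mean of only 2.52 CPM), the glucose transporter gene Slc2a1 (-1.12) and Bnip3 (-0.65) (camera adjusted p = 0.000677; adjusted p = 0.226 with an estimated correlation). Of the S phase list, Slbp (-0.69) and Mcm3 (-0.69) fell out of 15, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.226 with an estimated correlation).

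The other 18 lists had a camera adjusted p of 0.245 or more. None of the 15 cartilage matrix genes, 20 G2 and M phase genes, 9 Wnt targets, 13 mitochondrially encoded genes, 6 X inactivation and Y-linked genes or 6 X genes escaping inactivation passed. Markers of other cell types also held no passing member, with 7 neutrophil, 5 erythroid, 4 lymphoid and 3 endothelial genes measured, and the macrophage list had too few measured genes to be tested. Of the chondrocyte transcription and signalling list, Pth1r, Runx2 (2.35) and Mef2c (1.35) rose and Sox6 (-1.03) fell among 13, and of the fibrous matrix list 5 rose, led by the tenascin gene Tnc (2.94), and 1 fell among 15. Of the insulin-like growth factor axis, 4 of 11 rose and H19 fell, with a median of -0.10 where camera pointed up. Of the remaining lists, 2 of 17 dissociation and immediate early genes rose and 1 fell, 2 of 12 interferon response genes rose, 1 of 10 BMP targets rose (Id3, 1.19) and 1 fell (Grem1), 1 of 7 hedgehog targets rose (Ptch1, 1.42), and 2 of 6 sex steroid response genes rose and 1 fell.

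The count of 1300 rested on the ends of the series. It was 194 without the library labelled female day 2, 418 without male day 2, 432 without male day 35 and 434 without female day 35, and 5 without the 3 libraries whose sex-linked genes went against or mixed their labels, which leaves no library of day 2. It was 707 with at most 5% mitochondrial UMIs, a filter that matters because 36.5% and 26.2% of barcodes at day 14 and 24.6% in the library labelled female day 35 had been lost at 10%, and it was 830 without day 14.

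The change with the day was then fitted within chondrocyte-like cells. Matn3, a cartilage matrix gene, went from 266 and 356 CPM at day 2 to 1495 and 1841 CPM at day 35 in the libraries labelled male and female, though it did not pass within clusters 5 and 7 of the class taken alone. Fxyd2, a regulator of the sodium pump, went from 45.1 and 84.7 CPM to 875 and 697 CPM. Pth1r went from 130 and 126 CPM to 539.5 and 523 CPM. Dlk1 went from 406 and 362 CPM to 5.51 and 8.31 CPM, and Sulf2, an enzyme that trims heparan sulfate, from 262 and 311 CPM to 47.8 and 32.6 CPM. The class drew on different clusters over time: cluster 2, led by Dlk1, Rbp4 and Grem1, held 30.5% and 32.5% of mesenchymal cells at day 2 and 5.57% and 2.76% at day 35, while cluster 7, led by Serpina1b and C1qtnf3, held 2.79% and 3.10% and then 6.82% and 7.95%. Clusters 5 and 6 were most frequent at day 7, with 14.6% and 18.3% and with 15.3% and 11.9%.

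In this class 786 of 14899 genes passed (edgeR, adjusted p under 0.05, n = 8), of which 293 rose and 493 fell. The largest rises were Serpina1a (6.37, SE 1.16), Serpina1d (6.11, SE 0.97) and Serpina1b (5.26, SE 1.01), beside the coagulation factor gene F5 (4.51, SE 0.77). Next were Aspn, a small matrix proteoglycan (3.59, SE 0.75), Fxyd2 (3.35, SE 0.44), Apod, apolipoprotein D (3.32, SE 0.32), and the water channel gene Aqp1 (3.31, SE 0.52), with edgeR adjusted p from 0.000673 to 0.0222. The Serpina1 genes are neighbouring close copies on chromosome 12, so the share of each is uncertain. The largest falls were Dlk1 (-5.45, SE 0.39), the semaphorin gene Sema3e (-3.81, SE 0.22), Chrdl2 (-3.30, SE 0.60), the Wnt inhibitor gene Sfrp1 (-2.85, SE 0.41). Smaller were those of the phosphatase gene Dusp14 (-2.67, SE 0.33), Sulf2 (-2.62, SE 0.31), Grem1 (-2.58, SE 0.45) and Rian (-2.54, SE 0.23), with edgeR adjusted p from 6.69e-05 to 0.0125.

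Of 26 lists tested here, 7 passed camera with the preset correlation, none with an estimated correlation (lowest adjusted p = 0.546) and 3 with fry. Of the hypertrophy list, Runx3 (2.67) and Pth1r (2.14) rose out of 10, and 3 when adjusted over the list alone (camera adjusted p = 0.000854; adjusted p = 0.546 with an estimated correlation). Within clusters 2, 5 and 7 taken alone, Runx3 stood at 1.11, 0.85 and 0.79 and passed in none, and Pth1r at 0.46, 1.42 and 1.35 and passed in cluster 7. Of the cartilage matrix list, Matn3 (2.36) and Prelp (0.94) rose out of 15, also when adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.546 with an estimated correlation). Within the same clusters Matn3 stood at 2.17, -0.46 and 0.70 and Prelp at 1.24, 0.83 and 0.87, both passing in cluster 2 alone. Other members of the list fell within clusters 2 and 5, with Col2a1 at -1.19 and -1.95, Col11a2 at -0.94 and -1.88 and Col9a1 at -1.41 and -1.69, and did not pass in cluster 7 (-0.38, -0.01 and -0.13). Sterol and fatty acid synthesis had 5 of 12 genes that fell, and 7 when adjusted over the list alone, among them Sqle (-1.41), Insig1 (-1.24), Fdft1 (-1.14) and Hmgcs1 (-1.10) (camera adjusted p = 0.0167; adjusted p = 0.753 with an estimated correlation). Of the hypoxia and glycolysis list, Car9 (-2.91), Egln3 (-2.25) and Slc2a1 (-0.91) fell out of 14, also when adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.753 with an estimated correlation). The interferon-induced genes Ifit1 (-6.33) and Isg15 (-3.85) fell out of 10, and 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.753 with an estimated correlation). Of the immediate early list, Socs3 (1.57) and Zfp36 (1.37) rose and Nr4a1 (-1.23) fell out of 17, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.753 with an estimated correlation). None of the 20 G2 and M phase genes passed, nor when adjusted over the list alone, with the list as a whole pointing up (camera adjusted p = 0.000462; adjusted p = 0.753 with an estimated correlation).

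The remaining lists had a camera adjusted p of 0.104 or more, with single members that passed, such as the osteoblast transcription factor gene Sp7 (2.99), Ptch1 (1.91), Runx2 (2.04), H19 (-1.91) and the Wnt inhibitor gene Wif1 (-1.23). The count of 786 was 142 without the library labelled male day 2, 149 without female day 2, 397 without female day 35 and 518 without female day 14, and 4 without the 3 libraries whose sex-linked genes went against or mixed their labels, where Chrdl2, Notum, Slc2a1 and Wif1 changed direction. The fit without those 3 libraries holds no library of day 2, so these changes of direction do not cover that day. The count was 480 with coarser clusters, 235 with equal numbers of cells, 273 without day 14 and 1746 with no filter on low counts.

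Fibroblast-like cells were compared over days in 7 libraries, since the library labelled male day 2 had only 7 such cells. By edgeR 0 of 4953 genes passed for the day, with 235 at an unadjusted p under 0.05, and DESeq2 called 5. The genes of smallest p did not pass: the bone sialoprotein gene Ibsp had a log2 change of 4.67 (SE 0.76; edgeR adjusted p = 0.117), Spp1 of 4.58 (0.121), Fbln7 of 2.68 (0.117), Rbp4 of -2.30 (0.252), Sfrp2 of -3.86 (0.252) and the ribosomal pseudogene Rps3a3 of -7.21 (0.137). Without the 3 libraries in doubt, 2 genes were called and the changes of Ibsp and Sfrp2 turned direction, and the count was 15 without the library labelled female day 14 and 16 without day 14. Of 18 lists, cartilage matrix pointed down, which is not read as expression of the class, with 0 of 13 genes passing and 5 that fell when adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.566 with an estimated correlation). Col2a1 stood at 9166 CPM in the library labelled female day 2, the only library of that day in the fit, and at 56.8 to 1246 CPM in the others, against 342 to 2681 CPM in hematopoietic-like cells. The immediate early list pointed down with 0 of 17, also when adjusted over the list alone (camera adjusted p = 0.00575; adjusted p = 0.682 with an estimated correlation). No list passed fry. The fit without the 3 libraries in doubt held no library of day 2, so the turns of Ibsp and Sfrp2 do not cover that day.

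The sex comparison asked for genes that differed between libraries labelled female and male at matched days. In fibroblast-like cells 8 of 5995 genes passed (edgeR with day as a factor, n = 7), 3 higher and 5 lower under the label female. Xist was higher (11.76, SE 0.48; edgeR adjusted p = 7.92e-10), with 0 CPM in all 3 libraries labelled male that entered. Ibsp was higher, at 128, 78.5 and 466 CPM in the libraries labelled female and 5.22, 4.56 and 17.0 CPM in those labelled male at days 7, 14 and 35 (4.52, SE 0.39; edgeR adjusted p = 4.52e-06), as was the small GTPase gene Rrad (1.72, SE 0.31; 0.0325). Lower were the Y-linked gene Eif2s3y (-4.37, SE 0.74; edgeR adjusted p = 0.0189), Angptl7 (-2.13, SE 0.37; 0.0235), Slurp1 (-2.0, SE 0.29; 0.00382) and the tendon gene Tnmd (-1.39, SE 0.26; 0.0375). The count was 10 to 44 without 1 library each (44 without female day 35, 38 without female day 7, 31 without male day 7, 27 without male day 14, 22 without male day 35), 43 without the 3 libraries in doubt and 34 without day 14. DESeq2 called 3 genes, and 1 or 2 were called with no day term, with log2(day) as a number or with no doublet removal. The fit without the 3 libraries in doubt rests on the pairs of days 7 and 14 alone.

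Over all mesenchymal cells 0 of 17315 genes passed between the sex labels by edgeR, with 679 at an unadjusted p under 0.05, and DESeq2 called 10. Xist did not pass either (7.63, SE 2.42; edgeR adjusted p = 1.0), with 1251 CPM in the library labelled male day 2. The genes of smallest p were the muscle genes Acta1 (4.93), Tnnc2 (3.92) and Myoz1 (2.50) and, lower under the label female, Msmp (-0.84), the metallothionein gene Mt2 (-0.59) and Gldc (-0.50), with edgeR adjusted p from 0.463 to 1.0. Acta1 stood at 27.6 and 30.1 CPM in the libraries labelled female day 7 and day 14 and at 1.11 CPM or less in all others. The count was 28 without the library labelled female day 7, 2 without either library of day 2 and 1 without male day 14 or male day 35. It was 12 without the 3 libraries in doubt, a fit that rests on the pairs of days 7 and 14 alone.

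Of 27 lists, 8 passed camera between the sex labels, with 0 members called by edgeR, and 0 lists passed fry or camera with an estimated correlation. G2 and M phase genes pointed up under the label female (median 0.49; camera adjusted p = 2.47e-08; adjusted p = 0.555 with an estimated correlation), with 0 of 20 when adjusted over the list alone. S phase (0.000188; 1 of 15 when adjusted over the list alone), fibrous matrix (0.000405; 1 of 15), the insulin-like growth factor axis (0.0178; 2 of 11), lymphoid RNA (0.0306; 0 of 4) and sex steroid response genes (0.0452; 0 of 6) pointed up by camera adjusted p. BMP targets (0.0395; 0 of 10) and neutrophil RNA (0.0455; 1 of 7) pointed down. Their adjusted p with an estimated correlation ranged from 0.545 to 0.772.

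In chondrocyte-like cells 1 of 14899 genes passed between the sex labels, with 714 at an unadjusted p under 0.05, and DESeq2 called 1 other gene. The gene called by edgeR was the kallikrein gene Klk1 (7: 44225360 to 44229618), named here after its values were seen since its mean of 10.3 CPM was under the naming rule's minimum. Klk1 was higher under the label female (3.40, SE 0.37; edgeR adjusted p = 0.0291), at 25 and 52.0 CPM at days 7 and 14 against 3.85 and 1.59 CPM. It was not higher at day 2 (0.0975 against 0.139 CPM) or at day 35, with 0 CPM in both libraries. The call was lost without the library labelled male day 35 or female day 35, without day 14, with at most 5% mitochondrial UMIs, with no doublet removal, with finer clusters and with another day term. With equal numbers of cells it was lost too (1.70; edgeR adjusted p = 0.944), and 1 other gene was called. In contrast, 112 genes were called without male day 7, 105 without female day 7, 11 without male day 2, 5 without female day 2 and 2 without female day 14. The count was 12 without the 3 libraries in doubt, a fit that rests on the pairs of days 7 and 14 alone.

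The change with the day was also compared between the sex labels over all mesenchymal cells. By edgeR 0 of 17315 genes passed for the interaction, with 92 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest p stood with Xist (21.03, SE 2.36; edgeR adjusted p = 0.313), whose level was lowest under the label female at day 2 and highest under the label male at the same day.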

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

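The tests of free RNA, of swapped labels, of shifts between clusters, of blood RNA and of both explanations for the cells of day 35 were chosen after the results were seen, as were the orders of days that keep both libraries of a day together, whereas the test of hematopoietic-like cells and the other regroupings of libraries were fixed before theirs.

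A signal outside the comparisons, above its level in the other libraries of the same label, was seen in sex-linked transcripts: Xist stood at 1251 CPM in the library labelled male day 2, and Y-linked genes together stood at 144 CPM in the library labelled female day 2 and at 69.6 CPM in the library labelled female day 35. Free RNA shared between cells was argued against, since cells with both Xist and Y-linked UMIs were at most 10.5% as frequent as independent events would give in these libraries. A swap of the day 2 labels alone was argued against too, since 24.9% of cells in the library labelled female day 2 held Xist alone. What stays open is that these libraries may hold cells of animals of both sexes, whether pooled or mixed later: the rarer kind also made up 30.3% of hematopoietic-like cells with Xist or Y-linked UMIs alone in the library labelled female day 2 and 15.7% in female day 35. In male day 2, which this test did not cover, it made up only 5.37% (95% interval 3.4 to 8.0). Sex of the animals was itself a group of the design, so no biological explanation was tested, and every direction between sex labels above carries this doubt.

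The change of gene expression with the day in chondrocyte-like cells (786 genes) came with a turnover of clusters within the class. A shift between clusters as the whole cause was argued against, since of the 786 genes the 605, 566 and 577 measured within clusters 2, 5 and 7 taken alone kept a median of at least 46.9% of their change, though only 71, 60 and 29 passed there. Some agreement is built in, since these cells are part of the class. Direction was kept by 86.1%, 84.8% and 91.5% of these genes, against 57.9%, 56.8% and 58.7% of genes with an edgeR p over 0.5. Genes of that last kind changed little in the class, so they are no baseline for genes picked for their change. No conclusion is drawn from the comparison of directions. Clusters 6 and 16 of the class were not fitted, so the argument covers clusters 2, 5 and 7 alone. Part of the change may still be such a shift: Sulf2 stood at -0.81, -1.22 and -0.53 in these clusters, Grem1 at -0.07, -1.97 and -1.92, Fxyd2 at 0.85, 1.68 and 1.59 and Runx3 at 1.11, 0.85 and 0.79, none of them passing, Matn3 at 2.17, -0.46 and 0.70, passing in cluster 2 alone, and Serpina1b at -3.05 in cluster 2 (edgeR adjusted p = 0.160) while it rose in cluster 7 (5.78). RNA of blood cells was not excluded, because the erythroid gene Hbb-bs allowed up to 6.07% of free RNA in chondrocyte-like cells of the library labelled female day 7, with at most 1.15% in the other 7 and with 0.322% and 0.418% at day 35. The order of the days is not established by the count, and the age of the animals, which moves with the day, stays open, untested. Of 60 orders within sex label, 2 gave as many genes with the real one included (highest other 900). So did 3 of the 24 orders that keep both libraries of a day together (highest other 1271, with the order 2, 35, 14, 7). Those 24 orders keep the differences between days whole, so they bear on the order and cannot decide on chance.

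Lepr stromal-like and osteoblast-like cells went from 5 and 0 cells at day 2 to 4.60% and 5.95%, and 4.46% and 4.27%, of mesenchymal cells at day 35 in the libraries labelled male and female. Unlabelled cells that passed the sort were argued against as the whole source, since a TDTOMATO UMI was found in 13.2% (exact 95% interval 8.04 to 20.1) and 19.1% (12.2 to 27.7) of them after thinning, against 0.976% (0.359 to 2.11) of hematopoietic-like cells of the same day. More marrow in the day 35 libraries was not excluded. The hematopoietic-like share of kept cells goes against it as the whole cause, at no more than 1.32 times that of day 2. It was 2.73 and 6.40 times that of day 14 under the labels male and female. Lepr stromal-like and osteoblast-like cells together were at 26.4 times (95% counting interval 9.84 to 99.9) and 15.4 times (9.25 to 27.5) their share of day 14. Yet these blood cells had escaped a sort against CD45 and Ter119, so their share may not follow marrow. Endothelial-like cells went the other way, from 0% and 0.0393% of kept cells at day 2 to 0.228% and 1.41% at day 35. Descent from cells labelled at day 0, new labelling of cells that later express Sox9 and growth of the animals stay open, and none of them was tested. The shares rest on 1 library per sex label and day.

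In the library labelled male day 35, 3747 barcodes formed a cluster of their own outside the comparisons. TDTOMATO gave a signal in endothelial-like cells, which no comparison uses, at 21.1 CPM, from 7 UMIs in 70 cells, and 6 of the 7 UMIs were in the library labelled male day 14.

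Regroupings of the libraries bear on the other counts. For the day trend of all mesenchymal cells (1300 genes), 1 of 60 orders of the days within sex label gave as many, the real one, and the highest of the others gave 414. With both libraries of a day kept together, 4 of the 24 orders gave as many and the highest of the others gave 1919, with the order 2, 35, 14, 7. Such orders keep the differences between days whole, so they cannot decide on chance. The 3 orders that gave more genes keep day 2 first, so the count tells little about the order of the later days. Over all mesenchymal cells Hbb-bs allowed up to 21.1% of free RNA in the library labelled male day 14, where 4330 of its 4486 UMIs were in hypertrophic chondrocyte-like cells, and 5.42% in female day 7. Chance was not excluded for the sex labels in chondrocyte-like cells (1 gene), where 18 of 32 splits gave as many with up to 38, nor in fibroblast-like cells (8 genes), with 12 of 32 and up to 27. The fibroblast-like splits are not all distinct, since male day 2 is absent and female day 2 then adds nothing to the fit. The real split is thus counted there more than once. Over all mesenchymal cells (0 genes by edgeR, 679 at an unadjusted p under 0.05, 10 by DESeq2) 32 of 32 splits gave as many by construction, which says nothing about chance, and the highest gave 13. A further 3 splits of each could not be estimated. For the interaction (0 genes by edgeR, 92 at an unadjusted p under 0.05, 1 by DESeq2) 35 of 35 splits gave as many, again by construction. The split of days 7 and 35 from days 2 and 14 gave 4180 genes, which points to the structure of the libraries by day.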

How the results depend on the processing

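The fits without the 3 libraries whose sex-linked genes went against or mixed their labels, without day 14, with the cluster resembling free RNA, with Y-linked UMIs in place of the sex term and with unnamed clusters were chosen after the data were seen.

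Counts are given for the day trend in all mesenchymal, chondrocyte-like and fibroblast-like cells (1300, 786 and 0 genes), the sex effect in the same classes (0, 1 and 8) and the interaction (0). Leaving out 1 library at a time gave 194 to 1820, 142 to 1156 and 0 to 15 for the day trends, 0 to 28, 0 to 112 and 10 to 44 for the sex effects and 0 to 0 for the interaction. The mesenchymal day trend fell most without female day 2 (194), male day 2 (418), male day 35 (432) and female day 35 (434), and the chondrocyte-like one without male day 2 (142), female day 2 (149), female day 35 (397) and female day 14 (518). The highest counts were without female day 14 (15) for the fibroblast-like day trend, and for the sex effects without female day 7 (28), male day 7 (112) or female day 7 (105), and female day 35 (44). With 1 library of a day left, it is assumed to vary like the others. Without the 3 libraries in doubt the counts were 5, 4 and 2, then 12, 12 and 43, and 1. The falls of the first 2 are in part by construction, since no library of day 2 is left. For the sex effects male day 35 then has no partner, so the pairs of days 7 and 14 alone bear on those counts. Without day 14 they were 830, 273 and 16 for the day trends and 0 and 34 for the sex effect in chondrocyte-like and fibroblast-like cells. With DESeq2 the mesenchymal day trend gave 2013 genes and the fibroblast-like one 5, while the mesenchymal sex effect gave 10, the fibroblast-like one 3 and the interaction 1. With no filter on low counts, more genes were tested and 1746 and 36 passed for the day in chondrocyte-like and fibroblast-like cells, 197, 121 and 27 for the sex labels and 2 for the interaction. With day as a factor, day 35 against day 2 gave 4870, 2578 and 62 genes and the test of any difference 7447, 5194 and 232, where the contrast or test itself differs. At most 5% mitochondrial UMIs gave 707 in all mesenchymal cells and 0 for the chondrocyte-like sex effect. No doublet removal gave 1 for the fibroblast-like day trend, and 0 and 2 for the chondrocyte-like and fibroblast-like sex effects. Resolution 0.5 gave 480 for the chondrocyte-like day trend and resolution 2 gave 0 for its sex effect. Equal numbers of cells, which keeps fewer UMIs, gave 235 and 2 for the chondrocyte-like and fibroblast-like day trends and 1 for the interaction. With log2(day) as a number the chondrocyte-like and fibroblast-like sex effects gave 0 and 2, and with no day term 0 and 1. Except where the construction is named, the cause was not tested.

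Of the named genes, the values over all alternatives kept their direction in all mesenchymal cells (1382 on the same side of the threshold and 318 no longer past it, for 71 genes). In chondrocyte-like cells 876 stayed, 193 were no longer past it and 4 reversed, all without the 3 libraries in doubt: Chrdl2 (0.34), Notum (-0.31), Slc2a1 (0.35) and Wif1 (0.076). Likewise in fibroblast-like cells Ibsp (-0.47) and Sfrp2 (1.55) reversed, neither past the threshold in the main result. The fits without the 3 libraries in doubt hold no library of day 2, so these reversals do not cover that day. The named genes of the sex effects did not reverse, with 35 values no longer past the threshold in fibroblast-like and 10 in chondrocyte-like cells.

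Of the share trends, 1 passed in the main result, 0 with at most 5% mitochondrial UMIs, by highest marker score or with the cluster resembling free RNA, 2 with no doublet removal, 4 with unnamed clusters and 4 by edgeR on the cell counts. Without 1 library the count was 0 to 0, which says nothing about stability, since 1 class alone can then reach no adjusted p under 0.104 in the exact test. Pericyte-like (-0.088) and tenocyte-like cells (-0.50) reversed by highest marker score, and tenocyte-like cells (-0.40) with the cluster resembling free RNA. Of the gene lists, 0 passed with an estimated correlation for the mesenchymal day trend and sex effect and the chondrocyte-like and fibroblast-like day trends, against 9, 8, 7 and 2 with the preset one. Fry called 0 for the sex labels, 3 for the chondrocyte-like and 0 for the fibroblast-like day trend. The Sox9 change over all mesenchymal cells passed with day as a factor (-0.81) and was -0.36 with at most 5% mitochondrial UMIs and -0.76 to -0.45 without 1 library. The difference of its share of cells between day 35 and day 2 was -13.5 percentage points thinned to 1000 UMIs and -23.8 unthinned, against -19.0.

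Across days, no paired analysis was possible because the replicate number is the sex label itself, which the model already holds as a term, while between sex labels the libraries were matched by day throughout. Without the sex term 1750 genes were called in all mesenchymal cells. For fibroblast-like cells the fit without the library labelled female day 2, which leaves no day 2, and the fit with at most 5% mitochondrial UMIs, which leaves 1 library labelled male with at least 20 cells, were not run. The 718 mesenchymal cells of the library labelled male day 35 and the 29 fibroblast-like cells in it limit what can be seen at day 35.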

Other observations

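The classes and clusters in this part and the list of imprinted genes were chosen after the main results were seen.

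In articular or synovial-like cells 984 of 10401 genes passed for the day (edgeR, n = 8), of which 427 rose and 557 fell. The count was 73 without the library labelled female day 2, 141 without male day 2, 495 without male day 35 and 836 to 1081 without any other library. The complement inhibitor gene Serping1 (6.42, SE 0.82), the phospholipid transfer gene Pltp (5.84, SE 0.70), the phospholipase gene Pla1a (5.37, SE 0.86), Fgl2 (5.10, SE 0.95), the stromal marker Cd248 (5.06, SE 0.997) and Cyp1b1 (5.04, SE 0.79) rose, with edgeR adjusted p from 0.000788 to 0.00888. Cartilage genes fell, with Col9a1 at -2.75 (SE 0.22), Cnmd, which encodes the vessel inhibitor chondromodulin, at -2.63 (SE 0.28) and Col2a1 at -2.44 (SE 0.28), beside Dlk1 at -4.38 (SE 0.31), with edgeR adjusted p from 3.09e-05 to 0.000592. Of 14 cartilage matrix genes, 9 fell and 10 when adjusted over the list alone (camera adjusted p = 6.9e-08; adjusted p = 0.383 with an estimated correlation). Of 12 genes of sterol and fatty acid synthesis, 8 fell and 9 when adjusted over the list alone (camera adjusted p = 1.69e-07; adjusted p = 0.344 with an estimated correlation). Within the class, cluster 1, led by Cilp and Tesc, held 33.5% and 32.1% of mesenchymal cells at day 2 and 12.1% and 12.3% at day 35 in the libraries labelled male and female. Cluster 22, led by Fgl2 and Clic5, held 0.0846% and 0.0983% and then 3.34% and 1.62%. No fit within these clusters alone was made, so part of the changes in this class may be a shift between them.

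In tenocyte-like cells 20 of 10725 genes passed for the day (edgeR; 0 without either library of day 2, 2 without male day 35, 9 without female day 35, 13 without female day 14 and 14 to 28 without any other). Myoc (3.11, SE 0.52) and the matrix genes Fbln7 (2.23, SE 0.37) and Aspn (1.96, SE 0.35) rose, and Col2a1 (-2.46, SE 0.31), Col11a2 (-1.77, SE 0.29) and Acan (-1.46, SE 0.21) fell. Lars2 (2.98, SE 0.47) and Mir6236 (2.03, SE 0.27) also rose there, and outside the naming rule they rose in all mesenchymal cells (3.11 and 2.40) and in chondrocyte-like cells (3.01 and 2.38), with the cause not tested. Col2a1 stood at 2642 and 3052 CPM in tenocyte-like cells at day 2 and at 344 and 644 CPM at day 35 in the libraries labelled male and female, against 893 and 2681 and then 897 and 342 CPM in hematopoietic-like cells, so falls of cartilage genes in this class are not read as its own expression. Cartilage matrix genes fell there in 3 of 14 cases and in 9 when adjusted over the list alone (camera adjusted p = 7.82e-09; adjusted p = 0.0647 with an estimated correlation). Cluster 11 of this class held 0.338% and 1.18% of mesenchymal cells at day 2 and 3.48% and 2.49% at day 35. For cluster 4, the rest of the class, these shares were 8.84% and 9.34%, then 10.4% and 16.9%. Neither cluster was fitted alone, so part of the changes in tenocyte-like cells may be a shift between them. Hypertrophic chondrocyte-like cells, in 7 libraries, had 26 of 9102 genes past the threshold (edgeR; 1 without female day 35, 7 without male day 7, 8 without male day 35, 10 without female day 14, 12 without male day 14 and 14 without female day 7). Among them were the mineralization genes Ibsp (5.06, SE 0.70) and Alpl (2.43, SE 0.41) and the fructose transporter gene Slc2a5 (4.2, SE 0.62), which rose, and H19 (-2.83, SE 0.51), which fell. In this class day 2 rests on 40 cells of the library labelled female day 2, and no fit without that library was run. Cluster 3, led by Msmp, Stc1 and Myoc, had 140 of 10522 (edgeR; 7 without female day 2, 37 without male day 2, 76 without male day 35, 77 without female day 35 and 119 to 149 without any other). There 7 of the 12 genes of sterol and fatty acid synthesis fell, 10 when adjusted over the list alone (camera adjusted p = 1.33e-08; adjusted p = 0.250 with an estimated correlation).

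Dlk1, Rian, Mirg and H19, which all fell with the day, are imprinted, that is, expressed from 1 parental copy. A hypothesis is that imprinted genes fall as a group in the labelled cartilage cells, and it was tested on other imprinted genes, without these 4. In chondrocyte-like cells the 23 measured of 26 listed had a median log2 change of -0.53, with 18 below 0, 2 that fell by edgeR (Meg3 -2.28, Ndn -1.06) and 6 when adjusted over the list alone (camera p = 3.66e-05; p = 0.106 with an estimated correlation). In articular or synovial-like cells the 15 measured had a median of -0.81, with 13 below 0, 6 that fell and 8 when adjusted over the list alone (camera p = 1.38e-05; p = 0.00859 with an estimated correlation). This is consistent with the hypothesis in articular or synovial-like cells, whereas in chondrocyte-like cells it holds only with the preset correlation. Meg3 lies next to Dlk1 in the same imprinted region and is not independent of it, the age of the animals moves with the day, and both results come from the same libraries that raised the question. Both classes also drew on different clusters over time, and no fit within single clusters was made for articular or synovial-like cells.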
